A study of Mus musculus with 1 sample.

How the data were processed

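The data were 1 library of mouse bone marrow progenitors, captured with the BD Rhapsody microwell system and amplified by TAS-Seq, per the labels' protocols. Cells had been stained with 5 barcoded PE-streptavidin hashtags before pooling, with 100 cells loaded for A961, A962 and A964 and 15000 for A963 and A965, per the labels. The deposited table held whole-number counts per gene and cell, with cell totals that had not been equalised. The labels place a molecular identifier in read 1, but whether the counts are of molecules or of reads is not stated, nor are the aligner, the annotation or the counting tool. The number of values of 2 was 54.7% of the number of values of 1, so the counts may hold repeated reads of 1 molecule, and exact intervals cover counting error only. Genome build GRCm38, Seurat 4.2.0 and R 4.2.1 are listed without a role, per the submitters' processing notes.

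The table held 25661 genes and 10731 cells. Each cell's hashtag was taken from its name, per the file headers. Of the cells, 10535 carried a single hashtag, 190 were named doublets by the authors and 6, named for no detected hashtag, were not used. Cell totals ran from 8822 to 140994, so a minimum total appears to have been applied before deposit. Cells needed at least 500 genes and at most 20% mitochondrial counts, which removed 7 cells and left 10528. Summed counts were 1965440 for A961, 3100547 for A962, 118142775 for A963, 2360420 for A964 and 175876760 for A965. The transcript CT010467.1 took 2.29% of counts. Scrublet called 223 cells (2.12%) doublets; they stayed in, and removing them was an alternative.

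Cells of all hashtags were clustered together (scanpy 1.11.5, leidenalg 0.10.2) on log values scaled to 10000 counts, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Markers for 14 classes were fixed before the data were examined, and 3 of 251 marker and list genes (Cxcl2, Ncr1 and Mpig6b) were missing from the table. The naming thresholds were set after clusterings had been looked at. A cluster took the class with the most markers among its top 10 genes by fold, with at least 3 markers raised by 0.5 (log2) in at least 10% of cells, a leading marker raised by at least 1, no other class both in the top 10 and with a higher mean, and either several of its markers in the top 10 or 1 in the top 3. The last condition was added because the leading genes of cluster 7 went against the monocyte name that its markers gave. Unnamed clusters were 7, led by Cd7 and Irf8, 21, led by Ear2 and Apoe with neutrophil genes, and 22, led by Ace and Gngt2. They held 7.35% of A961, 5.77% of A962, 7.51% of A963, 5.48% of A964 and 9.14% of A965.

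No hashtag had a replicate, so no test between hashtags was made and no p-value is given. Shares have exact Clopper-Pearson intervals. Counts were summed over cells and scaled to CPM, and ratios have exact 95% counting intervals. Ratios of later granule counts per erythroid-like cell have 95% percentile intervals from a bootstrap over cells, which are not replicates. Log2 ratios were taken with 10 CPM added. Pairs were A965 against A963, and A961, A962 and A964 against each other; within classes, A965 was set against A963 where each had at least 100 cells. The genes named were, for each pair, among the 10 largest log2 ratios each way with at least 100 CPM and counts in at least 25% of cells of the higher hashtag, leaving out mitochondrial, ribosomal protein, Gm-number and Rik names. Members of the fixed gene lists are given as examples. Which of these genes to print, which list members to give and which genes to show by class were chosen after their values were seen.

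There were 17 gene lists, fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, as a description. Counts of members higher or lower by at least 1.5-fold also use the ratio with 10 CPM added. Printed folds have none added, so a member can pass 1.5-fold as a printed fold and not be counted. For shares of cells with a transcript, each cell was thinned to 8800 counts, which left out none. Coordinates are 1-based from GENCODE M21 (GRCm38), in which 24749 symbols (96.4%) were found.

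The ratio and list steps were tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold in each pair. All 100 had the right direction in each pair and at each size. For A965 over A963, over 25661 genes, the median measured fold was 1.93 and 3.70, and 95.0% and 92.0% of intervals held the true value. For A961 over A962, over 18360 genes, 96.0% and 93.0% did. For A961 over A964, over 17764 genes, 95.0% and 96.0% did, and for A962 over A964, over 18404 genes, 95.0% and 99.0%. A list of raised genes was at percentile 100 in each pair. Of 40 lists of unchanged genes, those outside percentiles 2.5 to 97.5 were 0 for A965 over A963 and for A961 over A964, and 1 for A961 over A962 and for A962 over A964. The simulation drew independent counts on the summed totals, the same model as the intervals, and its changed genes and lists had at least 100 CPM. It held no spread between cells, no repeated reads and no list members that vary together. It therefore checks the calculation and not how well intervals and percentiles suit these data.

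Alternatives fixed beforehand were no filter on cells, at least 1000 genes per cell, removal of Scrublet calls, Leiden resolutions 0.5 and 2, 1000 variable genes, 30 neighbours, another seed, classes of small hashtags taken from their nearest neighbours, median-of-ratios scaling, 1 CPM added, the mean of the cells' CPM, thinning, leaving out the deepest cell of each hashtag, leaving out list members under 10 CPM, and no minimum for named genes. Added after the data were seen were small-hashtag cells matched on Xist, the shared GMP-like cluster alone, each dendritic-like cluster alone, unnamed clusters given their closest class, and thinning within a class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.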

Results

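The data were 1 single-cell RNA-seq library from mouse bone marrow. Sorted progenitors were labelled with 5 DNA-barcoded PE-streptavidin hashtags (A961 to A965), pooled and captured together on 1 microwell cartridge. Per the labels, the pool held Lin-negative cKit-positive progenitors and GMP-MoPs from a naive mouse and from a mouse given lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation), and cMoPs from a naive mouse. GMP-MoP and cMoP are named there as monocyte progenitor populations. The labels do not say which hashtag was put on which population or mouse, so each comparison below is between hashtags, and no hashtag is given a treatment. There was 1 library and no replicate of any hashtag. No test between hashtags was possible. The intervals are exact 95% intervals that cover counting error only, except for bootstrap intervals over cells, which are named where given.

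The cells of A963 and A965 made up most of the library. After filtering, A963 held 4716 cells with a median of 20430.5 counts each, and A965 held 5567 cells with a median of 27205. The hashtags loaded with 100 cells were recovered in 68 cells for A961, 104 for A962 and 73 for A964, at medians of 25826.5, 27494 and 27801 counts. For the hashtags loaded with 15000 cells, the file held 31.5% of the loaded number for A963 (Clopper-Pearson interval 30.7 to 32.2%) and 37.1% for A965 (36.4 to 37.9%). Recovery was 68.0% for A961 (57.9 to 77.0%) and 73.0% for A964 (63.2 to 81.4%), and A962 was found in more cells than were loaded. The small hashtags were thus recovered at a higher share than the large ones. Part of their cells may be cells of the large pool carrying a small hashtag, in a number that is not known. Class shares and folds of the small hashtags below may include such cells. A further 190 cells were named as doublets by the authors and entered no comparison.

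X- and Y-linked transcripts separated the hashtags. Xist, the noncoding RNA that coats the inactive X chromosome of female cells (chromosome X, 103460366 to 103483254, GRCm38), reached 611 CPM (counts scaled to the same total for each group of cells) in A963 and 11.8 CPM in A965. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 6.46 CPM in A963 and 79.5 CPM in A965. With every cell thinned to 8800 counts, Xist was found in 85.4% of A963 cells (84.3 to 86.4%) and 5.51% of A965 cells (4.93 to 6.15%), and without thinning in 90.8% and 12.4%. Y-linked counts were found in 4.22% (3.66 to 4.83%) and 41.9% (40.6 to 43.2%) of thinned cells, and in 8.69% and 66.8% without thinning. Of the smaller hashtags, A961 and A962 lay nearer to A963, at 486 and 409 CPM of Xist, and A964 nearer to A965, at 59.7 CPM. High Xist in A963 and high Y-linked counts in A965 are what cells of a female and of a male mouse would give. Any difference between A963 and A965 therefore goes along with a difference in sex. Effects of mouse or treatment cannot be told apart from it.

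**Figure D1:**
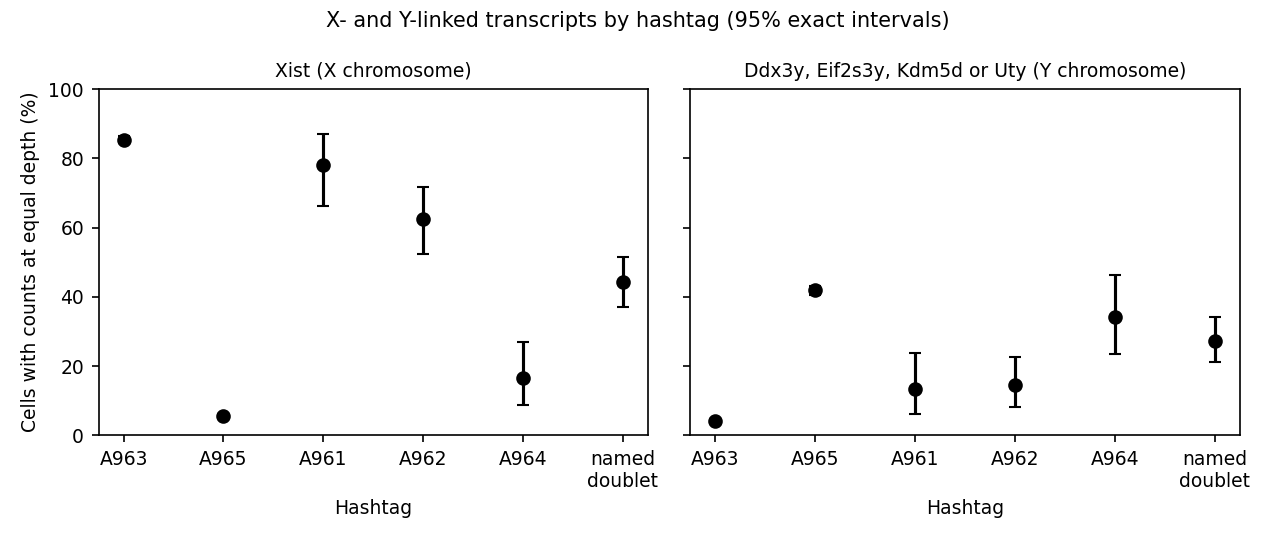
Share of cells of each hashtag, and of cells named as doublets, with Xist counts (left) and with counts of any of 4 Y-linked genes (right) after thinning each cell to 8800 counts; points are shares in percent and bars are exact 95% intervals. Xist was found in 85.4% of A963 cells and 5.51% of A965 cells, with A961 and A962 nearer to A963 and A964 nearer to A965.

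The first comparison asked which cell classes each hashtag held. Clustering of all hashtags together gave 23 clusters, of which 20 could be named from the markers. Erythroid-like cells, led by the globin genes and Car2 (carbonic anhydrase of red cell precursors), were 12.5% of A963 (11.5 to 13.4%; 588 of 4716 cells) and 2.48% of A965 (2.09 to 2.92%; 138 of 5567 cells), a 5.03-fold lower share in A965 (4.17 to 6.10). Stem-like cells were 4.83% of A963 and 2.93% of A965, and lymphoid-like cells 5.49% and 4.24%. Megakaryocyte-like cells (2.12% and 1.72%) and basophil/mast-like cells (1.17% and 1.13%) had share ratios whose intervals included 1. Dendritic-like cells were 8.33% and 7.20%.

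Neutrophil-like cells were the largest class in both, at 31.6% of A963 (30.2 to 32.9%) and 37.9% of A965 (36.6 to 39.2%). GMP-like cells, the granulocyte-monocyte progenitor class, with Mpo among the top 10 genes of each of its clusters, were 14.9% (13.9 to 16.0%) and 15.3% (14.4 to 16.3%). Monocyte-like cells were 11.6% (10.7 to 12.5%) and 17.9% (16.9 to 18.9%). Different clusters held most of these classes in the 2 hashtags. Neutrophil-like A965 cells lay mostly in clusters 1, 2 and 6 and A963 cells mostly in clusters 5, 8 and 18; monocyte-like A965 cells lay mostly in clusters 3 and 12 and A963 cells mostly in cluster 9, with 50 and 32 A963 cells in clusters 3 and 12; GMP-like A965 cells lay mostly in cluster 4 and A963 cells in cluster 11, with cluster 15, led by Elane, shared. Cluster 11 was led by Cd34 and Xist and cluster 4 by Ifitm1 and Mif. The borders between these 3 classes moved with the clustering. The A965 to A963 ratio of shares went from 0.879 to 1.94 for monocyte-like, from 0.989 to 1.34 for neutrophil-like and from 0.667 to 2.29 for GMP-like cells, so no direction is given for them, while the erythroid-like ratio stayed between 0.194 and 0.202. Stem-like and dendritic-like ratios each crossed 1 in 1 setting, at 1.28 with 1000 variable genes and at 1.43 with another seed. The 3 unnamed clusters held 7.51% of A963 and 9.14% of A965.

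**Figure D2:**
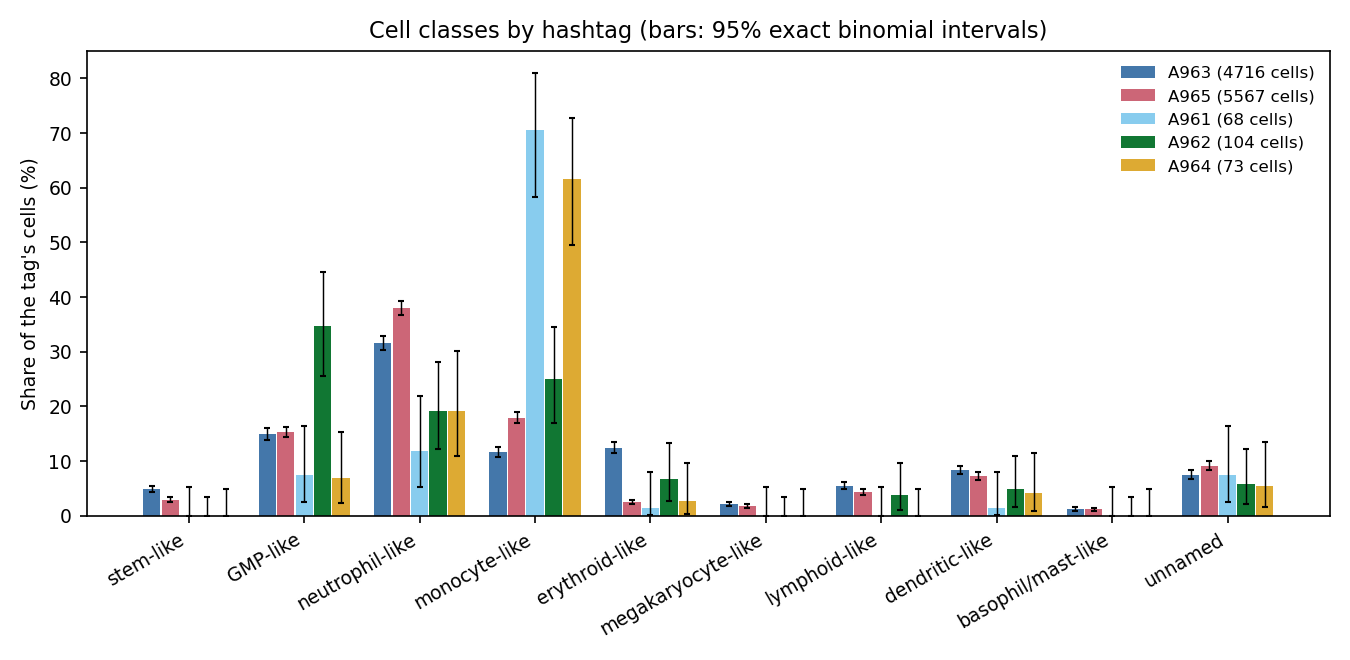
Share of each hashtag's cells (y axis, percent) in each cell class named from fixed markers; bars are coloured by hashtag and whiskers are exact 95% binomial intervals. Erythroid-like cells were 12.5% of A963 and 2.48% of A965, and monocyte-like cells were 70.6% of A961 and 61.6% of A964.

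In the 3 hashtags loaded with 100 cells each, monocyte-like and GMP-like cells together were 77.9% of A961, 59.6% of A962 and 68.5% of A964, the last falling to 46.6% at Leiden resolution 2. A961 was 70.6% monocyte-like (58.3 to 81.0%; 48 of 68 cells) and 7.35% GMP-like, and 43 of its cells lay in cluster 9, the monocyte-like cluster of A963. A962 was 34.6% GMP-like (25.6 to 44.6%; 36 of 104 cells) and 25% monocyte-like (17.0 to 34.4%), with 35 cells in cluster 11, the GMP-like cluster of A963. A964 was 61.6% monocyte-like (49.5 to 72.8%; 45 of 73 cells) and 6.85% GMP-like, with 25 cells in cluster 3 and 16 in cluster 12, the monocyte-like clusters of A965. Of the 15 nearest A963 or A965 neighbours of each cell, 75.5% carried A963 for A961, 58.7% for A962 and 16.2% for A964. These neighbours were drawn from 4716 cells of A963 and 5567 of A965. X- and Y-linked genes were not left out of the clustering, and Xist was among the leading genes of cluster 11. Neighbours and clusters may therefore follow Xist in part, and no setting without these genes was run. Neutrophil-like cells were 11.8%, 19.2% and 19.2% of A961, A962 and A964. Among cells with Xist counts, neutrophil-like cells were 3.70% of A961 and 5.80% of A962, and GMP-like cells 52.2% of A962. None of the 3 held a stem-like, megakaryocyte-like or basophil/mast-like cell, and a count of 0 has an exact upper bound of 5.28% in A961, 3.48% in A962 and 4.93% in A964. Clustered on 1000 variable genes, the split of A962 changed to 3.85% GMP-like and 55.8% monocyte-like.

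The second comparison set A965 against A963 over all cells. Of the 10 genes highest in A965, 3 belong to the interferon-induced transmembrane family. Ifitm1 (chromosome 7, 140967221 to 140969825) had 375 CPM in A965 and 111 CPM in A963, a 3.38-fold difference (3.32 to 3.45); Ifitm6 had 1543 and 565 CPM (2.73-fold, 2.71 to 2.75) and Ifitm3 1051 and 452 CPM (2.32-fold, 2.30 to 2.35). The 3 genes lie within one stretch of chromosome 7, and reads shared between such related genes could not be excluded. The other genes highest in A965 were Retnlg (2.90-fold), Lrg1 (2.44-fold), Ctsc, the protease that activates granule enzymes (2.38-fold), AA467197 (2.36-fold), Ccl9, a chemokine (2.04-fold), Anxa1 (2.01-fold) and S100a6 (1.97-fold).

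Of the genes highest in A963 after Xist, most belong to red cell precursors. The globins Hba-a1, Hbb-bt, Hba-a2 and Hbb-bs were 8.25-fold, 8.04-fold, 7.76-fold and 7.69-fold lower in A965; reads may be split between the copies of the alpha globin (Hba) and between those of the beta globin (Hbb). Car2 was 4.92-fold lower, Blvrb, which reduces biliverdin, 4.80-fold lower, Alad, an enzyme of haem synthesis, 4.32-fold lower, C1qtnf12 3.95-fold lower and Mgst3 3.42-fold lower. In the erythroid list, 14 of 15 members were at least 1.5-fold lower in A965 and the median log2 ratio was -2.10, below all 10000 random lists of matched expression (percentile 0). Here and below, such counts of list members take the ratio with 10 CPM added, unlike the printed folds.

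The granule lists were higher in A965. All-cell values also take in the mix of classes, with erythroid-like cells at 12.5% of A963 and 2.48% of A965. The azurophil granule list, many of whose members encode the first granule proteins of maturing granulocytes, had a median log2 ratio of 0.60 (percentile 100). Of its 10 members, 5 were at least 1.5-fold higher and none lower. Prtn3 was 1.59-fold higher (3232 and 2027 CPM), Elane 1.17-fold and Mpo 1.15-fold. Later neutrophil granule genes had a median of 0.44 (percentile 100), with 5 of 16 members at least 1.5-fold higher; Lcn2 had 6172 and 4260 CPM (1.45-fold). That median was 0.20 when every cell was thinned to the same depth. The unfolded protein response list (chaperones of the endoplasmic reticulum) had a median of 0.29 (percentile 99.97) with none of its 12 members beyond 1.5-fold, Sdf2l1 being 1.46-fold and Hspa5 1.29-fold higher; thinned, its median was 0.11. DNA replication genes had a median of -0.24 (percentile 0.070), with none of 12 beyond 1.5-fold and Mcm5 1.13-fold lower, and a median of -0.15 under median-of-ratios scaling. The interferon-stimulated list had a median of -0.04 (percentile 36.4) and none of its 16 members beyond 1.5-fold, and NF-kB and acute inflammation genes a median of 0.13 (percentile 100) with 1 of 15 higher, which was 0.25 with 1 CPM added and 0.23 without members under 10 CPM. The remaining medians were 0.13 for monocyte (percentile 98.0), 0.04 for MHC class II and dendritic cell (93.0), -0.06 for stem and multipotent (5.44), -0.05 for G2/M (50.3; 0.033 under median-of-ratios scaling), 0.001 for dissociation stress (78.2), -0.01 for myeloid transcription factor (66.1), -0.18 for megakaryocyte (0.060; -0.58 with 1 CPM added), -0.08 for lymphoid (6.93; -0.32), -0.05 for basophil and mast cell (27.2; -0.21) and 0.08 for macrophage genes (98.6).

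The third comparison set A965 against A963 within each class that held at least 100 cells of both, which were 7 classes. Ifitm1 was higher in A965 in 6 of them, 6.76-fold in GMP-like cells (6.50 to 7.03; 777 and 115 CPM) but 3.29-fold in their shared cluster 15 (2.81 to 3.87), 6.22-fold in monocyte-like (5.65 to 6.85), 5.33-fold in lymphoid-like (4.85 to 5.86), 3.49-fold in dendritic-like (2.92 to 4.19), 3.16-fold in neutrophil-like (2.91 to 3.42) and 2.34-fold in stem-like cells (2.25 to 2.43). In erythroid-like cells its ratio was 1.16 (0.944 to 1.41). In cluster 15 its levels were only 90.2 CPM in A965 and 27.4 CPM in A963. Ly6a, which encodes the surface antigen Sca-1 (chromosome 15, 74994877 to 74998031), was 10.1-fold higher in lymphoid-like cells (8.44 to 12.1; 306 and 30.5 CPM), 5.24-fold in dendritic-like (4.71 to 5.83), 2.98-fold in stem-like (2.65 to 3.35) and 2.33-fold in GMP-like cells (2.10 to 2.60). In monocyte-like cells it was 1.36-fold higher (1.22 to 1.51), and its ratio was 1.5 in erythroid-like (0.944 to 2.33) and 0.926 in neutrophil-like cells (0.813 to 1.06). Noct, which encodes the phosphatase nocturnin (chromosome 3, 51224447 to 51251644), was lower in A965 in 6 classes, from 1.87-fold in stem-like (1.70 to 2.05) to 1.5-fold in lymphoid-like cells (1.40 to 1.62), and had a ratio of 1.02 in neutrophil-like cells (0.974 to 1.08).

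**Figure D3:**
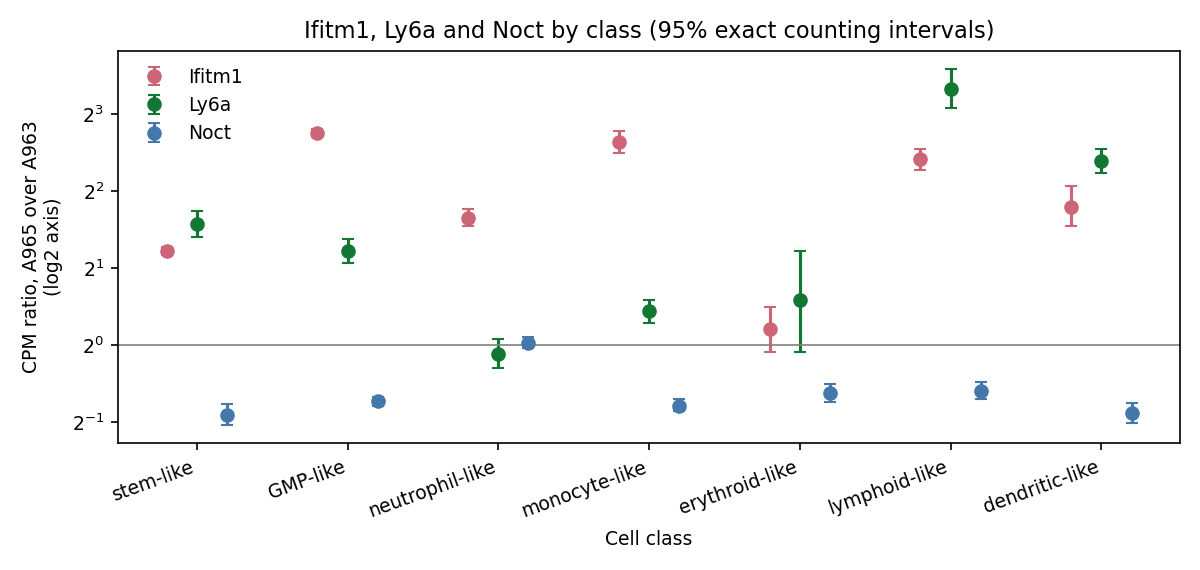
CPM ratio of A965 over A963 (y axis, log2 scale) of Ifitm1, Ly6a and Noct in the 7 classes compared; points are ratios of summed counts and bars exact 95% counting intervals. Ifitm1 was 6.76-fold higher in GMP-like cells (3.29-fold in the shared cluster 15), had an interval including 1 in erythroid-like cells, and Ly6a was 10.1-fold higher in lymphoid-like cells.

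In GMP-like cells, the myeloid genes Anxa1 (2.68-fold), Cybb, a subunit of the phagocyte oxidase (2.52-fold), and Lcn2 (2.43-fold) were higher in A965, and Cd93 (1.79-fold), Irf8, a transcription factor of monocytes and dendritic cells (1.59-fold), and F13a1 (1.58-fold) were lower. Anxa1 and Lcn2 are in the later granule list. Per cell thinned to 8800 counts, that list's summed counts had medians of 43 in A965 and 40 in A963, but means of 157.9 and 115.7. Cells with many such counts thus weigh on the class values. The unfolded protein response list had a median of 0.43 (percentile 100), with 2 of 12 members at least 1.5-fold higher, Hspa5 among them (1.57-fold; 734 and 467 CPM). The monocyte list had a median of -0.46 (percentile 0), with 4 of 12 members at least 1.5-fold lower with 10 CPM added. Its median was -1.50 when no cell was filtered out. In cluster 15 alone, which both hashtags shared, the unfolded protein response median was 0.49 and the monocyte median -0.06, and F13a1 was higher in A965 there (log2 ratio 0.78). Median counts were 46295 in A965 and 30900 in A963 for this class.

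Monocyte-like cells of A965 had more Wfdc17 (4.54-fold, 4.27 to 4.84), Gngt2 (3.43-fold), Itgam, the integrin CD11b (3.34-fold), Ear2, a ribonuclease with close relatives (3.18-fold), Chil3 (2.78-fold), Lcn2 (2.55-fold) and Ccl6 (2.53-fold), and less Cd93 (2.34-fold) and Aif1 (1.73-fold). Most of these cells lay in different clusters in A965 and in A963. Wfdc17 and Ccl6 led cluster 3, which held 518 cells of A965 and 50 of A963. No fold was taken within single clusters of this class, so these folds also reflect which clusters each hashtag filled. Later granule genes had a median of 0.37 (percentile 100), with 7 of 16 members at least 1.5-fold higher, which was 0.02 without Scrublet calls, and the interferon-stimulated list a median of 0.15 (percentile 99.99), with 3 of 16 higher. Per cell thinned to 8800 counts, the median sum of later granule counts was 65 in A965 and 46 in A963. Stem-like, lymphoid-like, dendritic-like and erythroid-like cells, which should lack these transcripts, had medians of 34 to 38. Megakaryocyte-like cells had 39 and 40, and basophil/mast-like cells 46 and 47. The A963 value was thus above all of these except the basophil/mast-like ones.

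In neutrophil-like cells, Ifitm3 (3.14-fold), S100a6 (2.59-fold), Srgn, the granule proteoglycan core (2.26-fold), Retnlg (2.17-fold), Prtn3 (2.07-fold) and Ifitm6 (2.04-fold) were higher in A965, and Camp, which encodes the cathelicidin of later granules, was 1.44-fold lower (41009 and 59073 CPM). Here too most cells lay in different clusters in A965 and in A963. Retnlg and Ifitm6 were among the top 10 genes of cluster 2, which held 676 cells of A965 and 76 of A963. Folds within single clusters of this class were not taken. The azurophil list had a median of 0.34 (percentile 99.97), which was -0.33 when 7 cells of high mitochondrial share were kept and all cells were clustered again, and the later granule list a median of -0.05 (percentile 1.47).

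In stem-like cells, Ifitm1 and Ly6a were joined by Serpina3g (2.53-fold) and Ube2c, a mitotic ubiquitin-conjugating enzyme (2.14-fold). The G2/M list had a median of 0.46 (percentile 100), with 3 of 12 members at least 1.5-fold higher with 10 CPM added. Without the added CPM, Ccnb1 also passed that fold (1.53-fold). Macrophage genes had a lower median in stem-like cells, -0.61 (percentile 0). With 10 CPM added, 6 of 9 members were at least 1.5-fold lower. The median was -1.64 with 1 CPM added, so its size depended on the amount added. Whether a few stem-like cells carried these counts was not examined. Mpo and Ctsg were 2.47-fold and 2.68-fold lower there. Mpo was found in 71.8% of A965 and 70.6% of A963 stem-like cells, and Ctsg in 45.4% and 43.4%. The azurophil list, to which both belong, had a median of -0.09 (percentile 6.36), with 3 of 10 members at least 1.5-fold lower and 1 higher. Lymphoid-like cells of A965 had more Adgrl4 (2.46-fold) and Ighm (1.80-fold) and less Myl10 (5.99-fold) and Mpo (2.25-fold). The lymphoid list had a median of -0.25 in them (percentile 0.090), with 5 of 14 members at least 1.5-fold lower and none higher. The MHC class II and dendritic cell list had a median of 0.25 (percentile 100), with 5 of 14 higher and none lower. Dendritic-like cells lay in cluster 13, led by Ly6d and Siglech (283 cells of A963 and 216 of A965), and cluster 17, led by H2-Aa (110 and 185 cells), so the mix of clusters differed. Ifi30 was 2.22-fold higher in A965 (log2 ratio 0.88 in cluster 13 and 0.81 in cluster 17) and Hspa8 1.78-fold higher (0.53 and 0.95). Hbb-bs and Hba-a1 were 21.4-fold and 12.8-fold lower, but 20 of 393 A963 cells held 93.0% of the globin counts of the class, and Hbb-bs was found in 33.7% of A965 and 32.8% of A963 cells. In this class the median of all well-counted genes was shifted by -0.14 (log2), and medians should be read against it. Erythroid-like cells of A965 had more H2-Q7, an MHC class I gene with close relatives (7.28-fold, 115 and 15.8 CPM). They also had more of the later granule list members Ngp (1.74-fold) and S100a9 (1.60-fold), and less Hba-a2 (1.56-fold). The median cell held 35 later granule counts in A965 and 34 in A963.

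**Figure D4:**
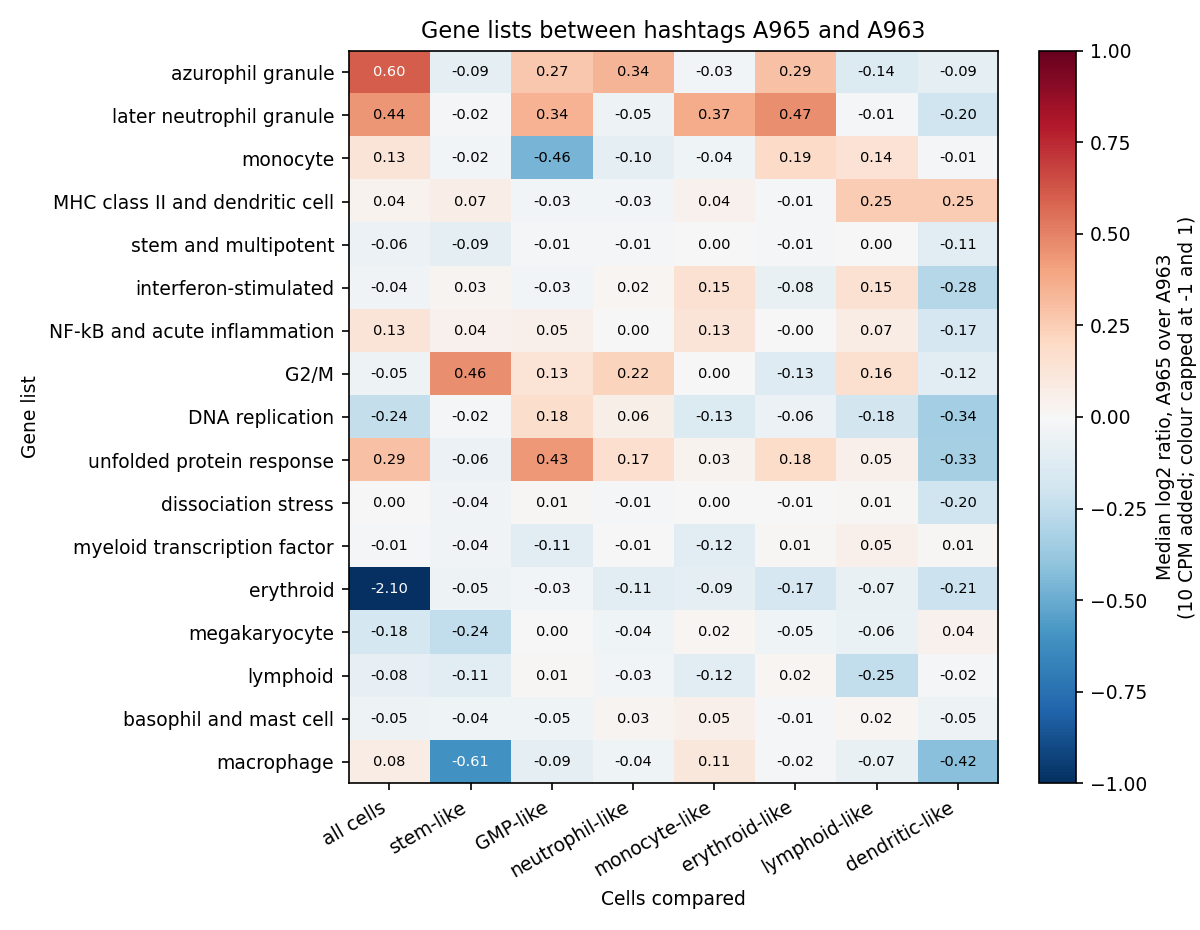
Median log2 ratio (10 CPM added) of A965 over A963 for 17 gene lists (rows) over all cells and within 7 cell classes (columns); red is higher in A965 and blue lower, with colour capped at -1 and 1 and each median printed. The erythroid list had a median of -2.10 over all cells and of -0.17 within erythroid-like cells, and the unfolded protein response list 0.43 in GMP-like and -0.33 in dendritic-like cells.

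The fourth comparison set the 3 small hashtags against each other, over summed counts of 1965440 for A961, 3100547 for A962 and 2360420 for A964. Klf4, a transcription factor of monocytes, was 2.86-fold higher in A961 than in A962 (2.30 to 3.56; 122 and 42.6 CPM), Crip1 2.64-fold, S100a4 2.62-fold, Itgb7 2.40-fold, Ahnak 2.36-fold, Prdx4 2.28-fold, S100a10 2.13-fold, Rbms1 2.08-fold, Lgals3 1.95-fold and Slpi 1.88-fold, and the chemokine receptor gene Ccr2 1.89-fold (1.67 to 2.13). The monocyte list had a median log2 ratio of 0.51 (percentile 100), with 5 of 12 members at least 1.5-fold higher. A962 had more Mpo (2.54-fold, 2.43 to 2.66; 2929 and 1153 CPM), Nkg7 (2.21-fold), Elane (2.13-fold), Lcn2 (1.92-fold) and Ifitm6 (1.84-fold, but with a log2 ratio of 0.016 for A961 over A962 among cells with Xist counts), and more of the globins, with Hbb-bt 8.13-fold higher. Hbb-bt was found in 35.6% of A962 and 30.9% of A961 cells, and 7 of 104 and 1 of 68 cells were erythroid-like. Cells of the large pool carrying a small hashtag, weighed below, could add to such folds. Matching on Xist would leave in those with Xist counts. Without Scrublet calls, which took the only erythroid-like cell of A961, the log2 ratio of Hbb-bt for A961 over A962 went from -2.96 to -5.41. The later granule list had a median of -0.55 (percentile 0; 7 of 16 members lower in A961), the azurophil list -0.28 (percentile 0), which was -1.14 among cells with Xist counts, and the erythroid list -1.21 (percentile 0), which was -2.40 without Scrublet calls.

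Ear2, Id2 and Wfdc17 were higher in A964 than in either of the others. Against A961, A964 had more Ear2 (3.64-fold, 2.93 to 4.57), Id2, an inhibitor of basic helix-loop-helix factors (3.14-fold), Hacd4 (2.76-fold), Fcnb (2.48-fold), Wfdc17 (2.31-fold), Mt1 (2.19-fold) and Chil3 (2.12-fold), and the later granule list had a median of -0.69 for A961 over A964 (percentile 0; 10 of 16 members lower), and of -1.97 between A961 cells with Xist counts and A964 cells without. A961 had more Xist (8.14-fold), Cd93 (3.82-fold), Bex6 (3.12-fold), Prdx4 (2.12-fold) and BC035044 (2.01-fold), and the monocyte list had a median of 0.36 (percentile 100). Hbb-bs was 2.27-fold higher in A961, but lower there (log2 ratio -1.75) once cells called doublets by Scrublet were removed. Against A962, A964 had more Ear2 (5.38-fold, 4.35 to 6.70), Wfdc17 (5.16-fold, 4.22 to 6.34), Ccl6 (3.26-fold), Ifitm1 (3.02-fold), Rnase6 (2.97-fold), Id2 (2.85-fold), Ctsc (2.57-fold), Lgals3 (2.52-fold) and Ifi30 (2.38-fold). A962 had more Hbb-bs (17.1-fold), Hba-a1 (15.8-fold), Srm (3.05-fold), Mpo (2.5-fold) and Noct (2.09-fold). The azurophil list had a median of 0.34 for A962 over A964 (percentile 100) and the erythroid list 0.90 (percentile 100), with 7 of the 104 A962 cells in the erythroid-like class. Xist differed between these hashtags too, so these values also compare cells unlike in it.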

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

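The tests of cells carrying the hashtag of another population, of shallow cells, and of free RNA in erythroid-like cells were chosen after the result was seen; the other 4 were written before. The 3 patterns weighed were picked after their values were seen.

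Some lists had medians of opposite sign in different classes when A965 was set against A963, with the middle range of their members on 1 side of 0 in each; the difference between classes was not tested. Counts of members in this paragraph take the ratio with 10 CPM added, without which more members can pass 1.5-fold. Of 12 DNA replication genes, 1 was at least 1.5-fold higher in GMP-like cells, 1 at least 1.5-fold lower in dendritic-like cells, and none passed 1.5-fold in lymphoid-like, monocyte-like or erythroid-like cells. Of 12 G2/M genes, 3 were higher by that fold in stem-like and 1 each in neutrophil-like and lymphoid-like cells, and of 12 unfolded protein response genes 2 were in GMP-like cells. Of 16 later granule genes, 7 were higher by that fold in monocyte-like, 6 in erythroid-like and 5 in GMP-like cells. In dendritic-like cells no member of these last 3 lists passed 1.5-fold. In dendritic-like cells the median of well-counted genes was itself shifted by -0.14. DNA replication genes had a median log2 ratio of 0.18 in GMP-like cells but -0.34 in dendritic-like, -0.18 in lymphoid-like, -0.13 in monocyte-like and -0.06 in erythroid-like cells, where the direction was lost (0.001) with cells thinned to 8800 counts. G2/M genes had medians of 0.46 in stem-like, 0.22 in neutrophil-like and 0.16 in lymphoid-like cells and of -0.12 in dendritic-like cells. The opposite direction was lost under some settings, since the dendritic-like median was 0.015 with median-of-ratios scaling and 0.32 in cluster 17 alone, and the lymphoid-like median -0.11 at Leiden resolution 2. Later granule genes had medians of 0.47 in erythroid-like, 0.37 in monocyte-like and 0.34 in GMP-like cells and of -0.20 in dendritic-like cells, close to the shift of that class, so an opposite direction is not shown. The monocyte-like median was 0.02 without Scrublet calls. The GMP-like median was 2.11 with no filter on cells, while the median GMP-like cell held 43 later granule counts in A965 and 40 in A963. Unfolded protein response genes had a median of 0.43 in GMP-like and -0.33 in dendritic-like cells.

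Cells named doublets entered no comparison, and 17.9% of them (12.7 to 24.1%; 34 of 190) held both Xist and Y-linked counts. The share among unfiltered cells of a single hashtag was 7.59% in A963, 8.49% in A965, 6.85% in A964 (2.26 to 15.3%), 11.8% in A961 (5.22 to 21.9%) and 11.5% in A962 (6.11 to 19.3%). The intervals of the last 3 overlap that of the doublets, and these shares were not matched for depth.

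Some A961 and A962 cells lacked Xist and held Y-linked counts, unlike most cells of those hashtags. Of 29 such cells, 37.9% (20.7 to 57.7%) were neutrophil-like or erythroid-like, against 8.7% of the 103 cells with Xist and without Y-linked counts. The share was 40.4% in A965, so cells of the large pool carrying a small hashtag could give this value. The interval also held the 21.9% of A964, so the test cannot tell large-pool cells from cells like those of A964. At 8800 counts per cell, 14.0% of A961 and A962 cells (9.1 to 20%) held Y-linked counts against 4.2% of A963, which argues against shallow cells as the whole source. The Y-linked share was 6.6 times as high (2.5 to 20.2) in cells without Xist as in cells with it, which argues against free RNA. No biological explanation was tested.

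Ifitm1 was higher in A965 in GMP-like cells, a class held mostly by different clusters in each hashtag. In the shared cluster 15 the difference was 3.29-fold (2.81 to 3.87), smaller than the 6.76-fold of the whole class but above 1.5. Different clusters are therefore not the whole source. Ifitm1 had 90.2 CPM in A965 and 27.4 CPM in A963 in cluster 15, against 777 and 115 CPM in the whole class. The A965 level of the class thus came mostly from its other clusters. At equal depth Ifitm1 was found in 75.0% of A965 and 33.1% of A963 GMP-like cells, a ratio of 2.26 (1.95 to 2.64), which argues against a few cells carrying it. Reads shared with the neighbouring family members were not tested and stay open. Xist and Y-linked transcripts differed between A963 and A965 as between female and male cells. That difference in sex, and any in mouse or treatment, cannot be told apart as causes.

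Of the later granule genes, 6 of 16 were at least 1.5-fold higher in A965 in erythroid-like cells, and none was lower. The median cell held 35 such counts in A965 and 34 in A963, a ratio of 1.03 (bootstrap over cells 0.94 to 1.11). This test was first framed for the difference, which free RNA alike in both hashtags cannot give, and was reassigned after its result was seen to the level in the median cell, with which free RNA is consistent. Without the cells highest in each hashtag, the ratio of means was 1.06 (bootstrap over cells 1 to 1.12), so the cells left out carried most of the difference. Cells are not replicates, so neither bootstrap covers differences between mice. What those cells are was not tested. No biological explanation was tested.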

How the results depend on the processing

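The settings matched on Xist, restricted to cluster 15, 13 or 17, giving unnamed clusters their closest class, and thinned within a class were chosen after the data were seen. Of 3353 values under alternatives, 2696 stayed within the interval or the members' middle range of the reported value, 637 moved beyond it and 20 reversed. Of the 846 that answer a comparison, 731 stayed, 108 moved and 7 reversed. That group is all shares, all lists between A965 and A963, and other lists within 0.1 of either end of the percentiles, a rule set after the values were seen. The erythroid-like share ratio stayed between 0.194 and 0.202. Requiring 1000 genes removed no cell and says nothing about stability, yet its 354 values are among those that stayed. A wide members' range also lets a large change count as staying. Later granule genes in monocyte-like cells, with a range of 0.009 to 1.19, counted as staying without Scrublet calls, although their median fell close to the lower end. The megakaryocyte-like ratio had no value at Leiden resolution 0.5. With no minimum CPM or share of cells, 9, 7, 4 and 10 of the 20 named genes remained for A965 over A963, A961 over A962, A961 over A964 and A962 over A964. No paired analysis was possible because there was 1 library. The cause of the changes below was not tested, except where a setting leaves out cells.

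Share ratios below are A965 over A963, shares are percent of a hashtag's cells, and lists are median log2 ratios. With no filter on cells, the neutrophil-like ratio was 1.01 and the monocyte-like 1.93; A965 shares were 22.9 monocyte-like, 16.8 GMP-like and 31.6 neutrophil-like; in GMP-like cells later granule genes had 2.11 and monocyte genes -1.50, azurophil genes reversed to -0.33 in neutrophil-like cells, and lymphoid genes had 0.03 in monocyte-like cells. With Scrublet calls removed, the GMP-like ratio was 0.830 and the monocyte-like 1.94; A965 shares were 23.4 monocyte-like and 12.6 GMP-like, and the A961 erythroid-like share 0; in GMP-like cells later granule genes had 1.36 and monocyte genes -1.42, azurophil genes had 0.15 in neutrophil-like and 0.001 in erythroid-like cells, lymphoid genes 0.028 in monocyte-like cells, G2/M genes reversed to -0.001 in lymphoid-like cells, and Hbb-bs for A961 over A964 reversed to -1.75. At Leiden resolution 0.5, A963 was 18.5 GMP-like and 28.5 neutrophil-like, A965 was 19.2 monocyte-like, 19.8 GMP-like and 33.5 neutrophil-like, and DNA replication genes had -0.22 in dendritic-like cells. At resolution 2, the GMP-like ratio was 0.918, the lymphoid-like 0.591, and the neutrophil-like (0.989) and monocyte-like (0.918) reversed; A963 was 11.2 GMP-like, A964 was 45.2 monocyte-like, 1.37 GMP-like and 46.6 either, and A965 was 10.4 monocyte-like, 10.3 GMP-like and 30.5 neutrophil-like; monocyte genes had -1.19 in GMP-like and DNA replication genes -0.26 in dendritic-like cells, and NF-kB genes (-0.005) and G2/M genes (-0.11) in lymphoid-like cells, G2/M genes (0.032) and Il7r (0.087) in dendritic-like cells reversed. With 1000 variable genes, the GMP-like ratio was 2.29 and the lymphoid-like 0.634, and the stem-like (1.28) and monocyte-like (0.879) reversed; A962 was 55.8 monocyte-like and 3.85 GMP-like, A963 was 20.1 monocyte-like, 6.74 GMP-like and 29.5 neutrophil-like, and A965 was 35.0 neutrophil-like. With 30 neighbours, the stem-like ratio was 0.828 and the GMP-like 1.17, A963 was 13.6 GMP-like and A965 16.1 monocyte-like. With another seed, the ratios were 0.667 for GMP-like, 1.34 for neutrophil-like and 1.87 for monocyte-like cells, and the dendritic-like reversed to 1.43; A963 was 20.5 GMP-like and 26.3 neutrophil-like, and A965 was 22.2 monocyte-like, 13.7 GMP-like and 35.2 neutrophil-like. With unnamed clusters given their closest class, the monocyte-like ratio was 1.38, A963 was 16.9 monocyte-like and 33.6 neutrophil-like, and A965 23.4 and 39.6.

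With the mean of the cells' CPM and with thinning, A965 over A963 had 0.20 and 0.20 for later granule, 0.11 and 0.11 for unfolded protein response, and -1.68 and -1.67 for erythroid genes, and the mean gave 0.28 for NF-kB genes in monocyte-like cells. Thinned within a class, NF-kB genes had 0.29 in monocyte-like cells, and in erythroid-like cells azurophil genes had 0.51 and DNA replication genes reversed to 0.001. With 1 CPM added, A965 over A963 had 0.25 for NF-kB, -0.58 for megakaryocyte, -0.32 for lymphoid and -0.21 for basophil and mast cell genes; within classes, macrophage genes had -1.64 in stem-like and -0.86 in dendritic-like cells, erythroid genes -0.26 in neutrophil-like cells, NF-kB genes 0.41 and lymphoid genes -0.31 in monocyte-like cells, monocyte genes 0.41 in erythroid-like cells, and interferon-stimulated genes -0.60 in dendritic-like cells. Without members under 10 CPM, NF-kB genes had 0.23. With median-of-ratios scaling, A965 over A963 had -0.15 for DNA replication, and G2/M genes reversed to 0.033; monocyte genes had 0.44 for A961 over A962; G2/M genes had -0.18 in erythroid-like cells; in dendritic-like cells MHC class II genes had 0.38, DNA replication genes -0.22, unfolded protein response genes -0.20, and G2/M genes reversed to 0.015. Without the deepest cell of each hashtag, later granule genes had -0.75 for A961 over A962 and -1.01 for A961 over A964. In cluster 15 alone, monocyte genes had -0.061 and unfolded protein response genes 0.49, and Slpi (0.31) and F13a1 (0.78) reversed. In dendritic-like cluster 13 alone, DNA replication genes had -0.26, unfolded protein response genes -0.21 and macrophage genes 0.18; in cluster 17 alone, MHC class II genes had -0.25, interferon-stimulated genes -0.60, DNA replication genes -0.18 and macrophage genes -1.22, and G2/M genes (0.32) and Il7r (0.10) reversed. Matched on Xist, A962 kept 69 cells; A961 was 85.2 monocyte-like, 3.70 neutrophil-like and 90.7 monocyte-like or GMP-like, and A962 52.2 GMP-like, 5.80 neutrophil-like and 75.4 monocyte-like or GMP-like; azurophil genes had -1.14 for A961 over A962, later granule genes -1.97 and monocyte genes 0.52 for A961 over A964, and Ifitm6 for A961 over A962 reversed to 0.016.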

Other observations

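All values here were picked after the data were seen, and none was tested. Cluster 7, left unnamed, was led by Cd7, Upb1, Ccnd1, Runx2, Irf8 and Bst2 and held 5.34% of A963 and 5.53% of A965. Cluster 22, led by Ace, Gngt2 and Adgre4, held 110 cells of A965 and 8 of A963. Cluster 21, led by Ear2 and Apoe with neutrophil genes, had a median of 40989.5 counts, and Scrublet called 109 of its 188 cells (58.0%) doublets.

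In dendritic-like cells of A963, 20 of 393 cells held 93.0% of the globin counts. Xist was found in 44.2% of the cells named doublets at 8800 counts per cell, and Y-linked counts in 27.4%.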
